A study of Mus musculus with 2 samples.

How the data were processed

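The series compared bone-marrow-derived macrophages with and without LPS on 2 Affymetrix Mouse Genome 430 2.0 arrays, 1 for each condition. Arrays were assigned to the control or the LPS group by their titles in the labels. The values deposited by the authors are linear intensity values, 1 per probe set and array, made with MAS5 per the submitters' processing notes. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal. The MAS5 version, any scaling target and detection calls are not given in the sources used here. The 2% trimmed means of the non-control probe sets were 204 on the control array and 187 on the LPS array, the means 311 and 305 and the medians 35.1 and 26.7, so no common scaling of these summaries is seen in the values. No column of values was left unused.

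The table held 45101 probe sets, of which 64 were array controls. Of the other 45037, 34945 were assigned to 1 gene in the platform annotation used here, 932 to several genes, and 9160 were not listed with a gene. Only probe sets with 1 gene were named. Of these, 34741 had a gene identifier in the RefSeq gene table of assembly GRCm38.p6, which was used for names alone and changed 0 symbols. Some well-known genes have no such probe set in this annotation and were not analysed here. No coordinates are given, because the sources used here name no genome build.

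Because no detection calls were used, each array's own median over non-control probe sets served as its floor (the 50th percentile). A signal under the floor was set to the floor before the ratio was taken, and the resulting fold is written as at least N-fold. No fold is given where both signals are under their floors. By construction the floor differs between the arrays, so a gene under the control floor whose LPS signal lies between both floors gets a small negative floored ratio although its LPS signal may be the higher one. A gene was measured if its probe set reached the floor on at least 1 array. For each gene the probe set with the highest mean log2 signal was used. Ratios are log2 LPS minus log2 control, as deposited, with no further scaling. With 1 array per condition there is no estimate of spread between replicates, so no p-value was computed and genes were counted by size, at least 2-fold higher or lower. As a technical gauge only, 4494 genes had 2 or more probe sets measured on both arrays, and the median SD of their log2 ratios was 0.28. Among 2112 genes past 2-fold with 2 or more measured probe sets, 92.8% had all of them in 1 direction.

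Before the data were examined, 30 pathway lists, 10 lists of markers of other cell types, the size threshold and the rule for named genes were fixed. The rule takes the 12 genes with the highest and the 12 with the lowest ratio, provided that the median of a gene's probe sets has the same direction, 11 genes named in advance (Tnf, Il6, Il1b, Il10, Nos2, Cxcl10, Ifnb1, Tlr4, Cd14, Csf1r and Adgre1), and from each list up to 4 members with the largest ratios in size and the 1 with the largest ratio against the list's median. For lists with at least 3 measured members the percentile of the median log2 ratio was found among 10000 random lists of the same size, matched on mean log2 signal in 20 bins. A list is called above or below the random lists outside the 2.5th and 97.5th percentile, bounds that were set after the values were seen. With 37 such lists about 1.9 would lie outside by chance. Lists overlap, and their genes are not independent. FoxO-induced genes, circadian clock genes, early myeloid progenitor markers and T cell receptor complex genes are 4 further lists that were written after the ratios were seen and appear only in the closing observations.

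Alternatives chosen before the data were examined were floors at the 35th and 65th percentile, a pseudocount of 16 with no floor, quantile normalization, median-centred ratios, loess of the ratio on mean log2 signal (span 0.4), the median of a gene's probe sets, plain probe sets alone (names ending in _at with no s, x or a before it), and thresholds of 3-fold and 1.5-fold. Scaling to the hybridization controls, scaling to the poly-A controls and a restriction to genes at or above the floor on both arrays were added after the data were seen. Hybridization controls are added with the hybridization mix and poly-A controls before labelling in the standard Affymetrix protocol. Their use in these 2 samples is not stated in the sources used here.

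The steps were tested on simulated arrays for the LPS against control comparison, with 11038 genes, noise of SD 0.3 in the log2 ratio, a shift of -0.4 and 200 changed genes. As deposited, 70.0% of genes set 3-fold higher and 100.0% of genes set 3-fold lower passed 2-fold, and 2.2% of unchanged genes did. With median centring these were 98.0%, 100.0% and 0.1%. The simulated shift was the same at every brightness, and equal numbers of genes were set higher and lower. The real shift varied with brightness and far more genes differed, mostly downwards, so these rates do not carry over to the real arrays. A simulated list lowered by 1 log2 unit had percentile 0.00, and an unchanged list 2.64. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.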

Results

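Bone-marrow-derived macrophages of C57BL6 mice were grown with macrophage colony-stimulating factor (M-CSF), the cytokine that drives bone marrow precursors to become macrophages, and were left untreated or treated with lipopolysaccharide (LPS). LPS is a component of the outer membrane of Gram-negative bacteria that is sensed by Toll-like receptor 4 (TLR4). Total RNA of each condition was labelled with biotin and hybridized to a Mouse Genome 430 2.0 microarray (Affymetrix), on which each gene is read by 1 or more probe sets. The labels give 1 control array and 1 LPS array, and they state neither the dose nor the duration of the LPS treatment. There are therefore no replicates and no test: every difference below lacks a replicate check and describes these 2 arrays, and this number of arrays limits the precision of every value. The question the design poses is which transcripts differ between untreated and LPS-treated macrophages.

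Of 18193 genes with a probe set assigned to 1 gene, 11722 were measured, meaning that the signal reached the floor (the array's own median signal) on at least 1 array. Of these, 9822 reached it on both arrays, 1055 only on the LPS array and 845 only on the control array. The floor was 35.1 signal units on the control array and 26.7 on the LPS array. Over the 19862 probe sets at or above the floor on both arrays, Pearson's r between the log2 signals was 0.832, a correlation across probe sets, which are not independent replicates. The ratio of the 3′ to the 5′ probe set, a sign of RNA integrity, was close on the control and LPS arrays, at 1.15 and 1.13 for Actb and 0.787 and 0.803 for Gapdh.

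The LPS array differed widely from the control array, and the largest differences on its higher side included cytokine, chemokine and acute-response genes. As deposited, 964 genes were at least 2-fold higher and 3076 at least 2-fold lower on the LPS array, so that 23.9% of the genes past this size were higher. After centring the ratios on their median, the numbers were 1513 higher and 1818 lower, or 45.4% higher. The difference arises from an array-wide shift: the median measured gene had a log2 ratio (LPS over control) of -0.42. The shift was larger among dim than bright genes, with a median of -0.61 at a mean log2 signal of 7 to 9 and -0.08 at 11 to 14. The control RNAs added at hybridization had a median of -0.05 (SD 0.12 over 18 probe sets), and the control RNAs that are added before labelling in the standard protocol had a median of -0.29 (SD 0.23 over 24 probe sets). Quantile normalization put 42.9% of the genes past 2-fold on the higher side, loess 45.4% and scaling to the controls added before labelling 37.7%. Ratios below are as deposited, and for the gene lists, counts after median centring stand beside them where they differ.

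**Figure D1:**
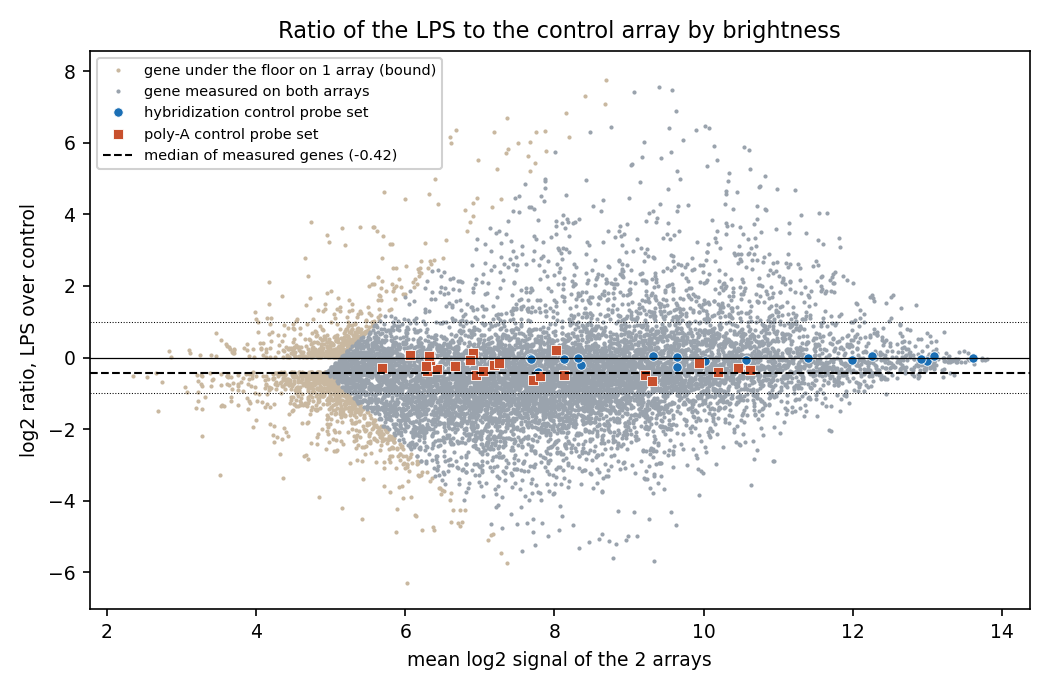
Log2 ratio of the LPS over the control array (y axis) against the mean log2 signal of both arrays (x axis), with 1 point per measured gene other than those under the control floor whose floored ratio was 0 or less. Points are tan where the gene was under the floor on 1 array so that the ratio is a bound, blue for hybridization controls and red for poly-A controls. Dotted lines mark 2-fold, and the dashed line marks the median of measured genes, -0.42, which lies below the median of the hybridization controls, -0.05.

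The 12 genes with the highest ratios included several secreted mediators. Il6, a cytokine of the acute-phase response, had a signal of 0.81 on the control array, under the floor, and 8178 on the LPS array, at least 233-fold higher. The chemokine genes Ccl12 and Cxcl9 were at least 216-fold and at least 104-fold higher, and Ccl7 was 171-fold higher. The other Cxcl9 probe set was at 3.46 on the log2 scale. Il1b, which encodes interleukin-1 beta, went from 56.8 on the control array to 10215 on the LPS array, 180-fold higher, and the early activation marker Cd69 was 191-fold higher. Lcn2, which encodes a protein that binds bacterial iron carriers, was at least 158-fold higher. Acod1, whose enzyme makes itaconate, was 119-fold higher, and Socs3, a feedback inhibitor of cytokine signalling, was 89.3-fold higher. The remaining ones were AA467197 (at least 136-fold), the formyl peptide receptor gene Fpr2 (87.8-fold) and the actin-bundling gene Fscn1 (at least 114-fold), whose 4 measured probe sets ranged from 0.72 to 6.83 on the log2 scale.

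The 12 genes with the lowest ratios included receptors, transporters and regulators of growth. Cxcr4, the receptor for the chemokine CXCL12, had a signal of 2126 on the control array and 2.01 on the LPS array, at least 79.7-fold lower. Arhgap19 was at least 53.3-fold lower. Sesn1, a stress-responsive inhibitor of mTORC1 signalling, was 51.8-fold lower, and Slc40a1, which encodes the iron exporter ferroportin, was 49.1-fold lower. Dbp, a transcription factor gene of the circadian output, was at least 44.0-fold lower. Gpr34 was 42.4-fold, the ceramide kinase gene Cerk 39.9-fold, Tcp11l2 37.7-fold, the amino acid transporter gene Slc43a2 37.2-fold, Tmem86a 35.9-fold, Lhfpl2 35.1-fold and the kinase gene Mknk2 34.5-fold lower. The 4 probe sets of Lhfpl2 ranged from -5.13 to -0.42 on the log2 scale. On that scale the 2 of Arhgap19 were at -5.74 and -2.06, the 4 of Sesn1 ranged from -6.19 to -2.20, and the 3 of Slc43a2 from -5.22 to -3.03.

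**Figure D2:**
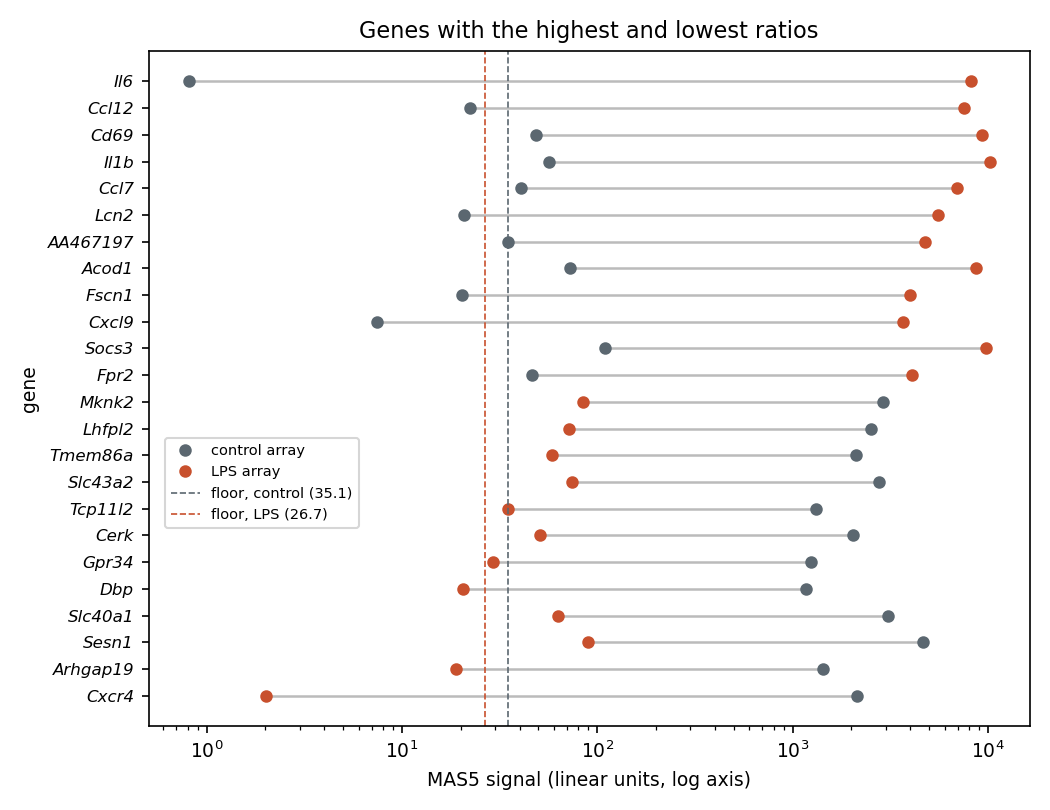
MAS5 signal on the control array (grey) and the LPS array (red) for the 12 genes with the highest and the 12 with the lowest ratios, on a log axis in linear signal units, with 1 value per array and no error bars because each condition has 1 array. Dashed lines mark the floors, 35.1 for control and 26.7 for LPS, and a point left of its floor makes that gene's fold a lower bound.

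Genes of the NF-kB pathway and secreted mediators were higher on the LPS array. Of 13 measured NF-kB subunits and feedback genes, 12 were at least 2-fold higher and 0 lower, with a median log2 ratio of 2.69, and 13 were higher after median centring. Tnfaip3, which encodes the NF-kB inhibitor A20, was 30.5-fold higher, the IkB family gene Nfkbiz 24.9-fold, Nfkbie 11.5-fold and Traf1 at least 55.1-fold. Of 14 measured inflammatory cytokines, 9 were higher, 0 lower and 5 within 2-fold (median 2.87, and 3.87 with the floor at the 65th percentile), with 10 higher after median centring. They included Tnf, 68.3-fold higher, and Il12b, which encodes the p40 subunit of interleukins 12 and 23, at least 64.7-fold higher. Ifnb1, which encodes interferon beta, had signals of 29.1 on the control array, under the floor, and 37.1 on the LPS array. Of 18 measured chemokines, 16 were higher and 0 lower (median 5.46, but 4.05 with only genes at or above the floor on both arrays, 4.48 with the floor at the 65th percentile and 4.59 with the median of each gene's probe sets), with Ccl2 85.4-fold and Cxcl10 55.9-fold higher, while Ccl6 had a log2 ratio of -0.23, which turns positive after median centring and after scaling to the poly-A controls. The medians of these 3 lists lay above all 10000 random lists matched on signal.

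Inhibitors of inflammation were higher on the same array. Of 14 measured feedback inhibitors, 8 were at least 2-fold higher and 0 lower (median 2.37, above all 10000 random lists, but 1.51 with plain probe sets alone), and 10 were higher after median centring. The phosphatase genes Dusp2 and Dusp1 were 48.2-fold and 35.7-fold higher, the interleukin-1 receptor antagonist gene Il1rn 45.8-fold and Il10 14.1-fold, whereas Dusp4 had a log2 ratio of -0.99 with its LPS signal under the floor. The immediate-early and AP-1 genes were mixed: of 18 measured, 6 were higher, among them Ier3 (5.95-fold) and Junb (5.56-fold), and 3 were lower, among them the transcription factor genes Klf2 (5.41-fold) and Egr3 (at least 5.65-fold, with its other probe set at -0.44). Their median of 0.87 was at percentile 99.99 of the random lists, and 10 were higher after median centring. Of 14 measured genes listed as primary LPS response genes, 12 were higher (median 2.56, and 4.18 with plain probe sets alone), for example Cxcl2 at 36.9-fold, while Btg2 had a log2 ratio of -0.10, positive under every scaling tried except that to the hybridization controls. Of 12 listed as secondary response genes, a class defined by a need for newly made proteins, 10 were higher (median 5.90), and 11 were higher after median centring. That need was not measured here and may not hold for every listed gene, such as Ccl5, which was 84.9-fold higher. Both of these lists lay above all 10000 random lists and share members with the lists above.

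Interferon-stimulated genes stood higher as a complete group. All 27 measured members were at least 2-fold higher on the LPS array, with a median log2 ratio of 3.71, above all 10000 random lists. The antiviral genes Oasl1, Mx1 and Mx2 were 65.4-fold, 60.4-fold and at least 46.2-fold higher, and Iigp1, which encodes an immunity-related GTPase, was 48.1-fold higher. Of 12 measured genes of MHC class I presentation, 7 were higher and 0 lower (median 1.27, percentile 99.98), with 8 higher after median centring. These included the transactivator gene Nlrc5 (8.94-fold), the peptide transporter genes Tap1 (6.64-fold) and Tap2 (4.44-fold) and the immunoproteasome gene Psmb10 (3.93-fold). H2-K1, from a multigene family whose members can share probes, had a log2 ratio of -0.01 that turns positive under 3 of the 5 scalings.

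MHC class II genes did not stand apart. Of 9 measured, 0 were higher and 1 was lower (0 after median centring), and the median of -0.13 (percentile 67.9) turns positive under quantile normalization, median centring, loess and scaling to the poly-A controls. The lower one was the class II transactivator gene Ciita, at least 2.37-fold lower from a control signal of 63.1. H2-Ob and H2-Oa were near the floor, H2-Ob with signals of 39.1 and 19.2, under the floor, and H2-Oa with 34.6, under the floor, and 49.8, and H2-DMa was at -0.38, which turns positive under quantile normalization, median centring and loess. Of 13 measured costimulatory and activation surface molecules, 10 were higher and 0 lower (median 3.27, above all 10000 random lists), with 11 higher after median centring. Cd40 was 82.6-fold higher, Tnfsf9, the ligand of 4-1BB, 31.3-fold and the adhesion molecule gene Vcam1 22.0-fold. Cd80, with signals of 114 and 113, differed little.

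Genes of LPS and TLR sensing were divided. Of 16 measured, 7 were higher and 2 lower (median 0.49, percentile 99.84), and after median centring 8 were higher and 1 lower. The adaptor and kinase genes Myd88 and Irak2 were 4.41-fold and 6.88-fold higher, the receptor genes Tlr3 and Tlr1 9.92-fold and 3.56-fold, and the LPS co-receptor gene Cd14 2.59-fold. Tlr4, the LPS receptor gene itself, was 2.96-fold lower. Of 15 measured antimicrobial and effector enzymes, 10 were higher and 0 lower (median 3.65, above all 10000 random lists), with 12 higher after median centring. Ptgs2, which encodes cyclooxygenase-2, was at least 82.3-fold higher and the acute-phase gene Saa3 58.9-fold. Nos2, the inducible nitric oxide synthase gene, was at least 12.3-fold higher. Slc11a1 had a log2 ratio of -0.89. Of 14 measured inflammasome and cell death genes, 8 were higher and 2 lower (median 1.13, above all 10000 random lists). Among them were Casp4 (8.33-fold), whose product senses cytosolic LPS, Aim2 (7.36-fold), Mlkl (6.97-fold) and Fas (6.11-fold), while Pmaip1 was 2.45-fold lower. After median centring 9 were higher and 0 lower.

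Among 13 measured phagocytic, scavenger and complement genes, 6 were higher and 2 lower (median 0.67, percentile 99.69), with 7 higher and 2 lower after median centring. Complement factor B (Cfb) was at least 31.5-fold higher, the scavenger receptor gene Msr1 7.08-fold (4 probe sets, from 0.60 to 2.82) and the Fc receptor gene Fcgr4 12.9-fold. Marco, another scavenger receptor gene, was higher by at least 4.32 on the log2 scale, while Cd300lf was 4.72-fold lower. With only genes at or above the floor on both arrays, this list had a median of 0.07 at percentile 83.0. Of 11 measured proteases and matrix remodelling genes, 5 were higher and 2 lower (median 0.56, percentile 99.33), with 5 higher and 0 lower after median centring. The collagenase gene Mmp13 was 38.8-fold higher, Mmp14 26.0-fold, Serpinb2 at least 12.6-fold and the protease inhibitor gene Timp1 7.90-fold, and Timp2 was 2.66-fold lower. This list lay inside the range of the random lists in 3 of the 11 alternatives, at 96.4 in the lowest, and its median was 1.34 with the floor at the 65th percentile.

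Genes of macrophage identity mostly lay within 2-fold. Of 18 measured, 3 were higher, 3 lower and 12 within 2-fold, with a median of -0.24 (percentile 20.9) that turns positive after median centring and after scaling to the poly-A controls. After median centring 3 were higher and 1 lower. The M-CSF receptor gene Csf1r had signals of 9710 and 7724, a log2 ratio of -0.33 that turns positive after median centring. Adgre1, which encodes F4/80, had signals of 6967 and 7338, a log2 ratio of 0.07 that turns negative under quantile normalization and loess. The myeloid transcription factor genes differed, with Cebpa 27.2-fold lower and Spi1 2.26-fold higher. The high-affinity Fc receptor gene Fcgr1 was 4.02-fold higher and the fractalkine receptor gene Cx3cr1 2.53-fold lower.

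Genes of alternative activation, the state that interleukin-4 induces, had a low median but moved both ways. Of 12 measured, 3 were higher and 4 lower (median -0.87, percentile 1.27), and after median centring 3 were higher and 2 lower. Arg1, Retnla and Mgl2 were under the floor on both arrays, so the median does not cover them, and Chil3 was at 0.18. The nuclear receptor gene Pparg was at least 9.89-fold lower and the lectin gene Clec10a 2.92-fold lower, whereas the interleukin-4 receptor gene Il4ra was 9.33-fold higher and Tgm2 4.30-fold higher. The percentile rose as far as 7.36 among the alternatives, and 3 of the 11 put it inside the range of the random lists. Of 18 measured chemoattractant, cytokine and purine receptors, 4 were higher and 8 lower (median 0.08, percentile 96.8, and 98.6 with the median of each gene's probe sets), and after median centring 9 were higher and 6 lower. The median turned to -0.53 with the floor at the 65th percentile and to -0.10 with plain probe sets alone, so its direction was not settled. Ccrl2 was 17.3-fold higher and the ATP receptor gene P2rx7 11.6-fold lower (3 probe sets, from -3.53 to -1.29). Of 8 measured osteoclast genes, 2 were higher and 3 lower (median -0.62, percentile 39.6, and a median of -1.22 with only genes at or above the floor on both arrays), but 3 were higher and 2 lower after median centring. Nfatc1, the master regulator of osteoclast formation, was 8.23-fold lower by its brightest probe set, although its 5 probe sets ranged from -3.04 to 0.02. Atp6v0d2 was 6.10-fold lower, while Tnfrsf11a, the RANK gene, was 2.35-fold higher (its other probe set at 0.75) and Acp5 at least 5.10-fold higher.

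Cell cycle genes were lower on the LPS array in a body. Of 17 measured DNA replication genes, 0 were higher and 14 lower, with a median log2 ratio of -1.73, and of 17 measured mitosis genes 0 were higher and 15 lower, with a median of -2.06. After median centring the numbers lower were 12 and 14. Both medians lay below all 10000 random lists. Rrm2, a subunit of the enzyme that makes deoxynucleotides, was 13.4-fold lower, the replication licensing genes Cdt1 and Mcm7 10.3-fold and 6.15-fold, and the cyclin gene Ccne2 8.59-fold. Among mitosis genes, Cdc20 was 10.5-fold lower, the spindle checkpoint gene Bub1b 9.46-fold, the motor gene Kif11 7.70-fold and the kinase gene Aurkb 6.58-fold.

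Glycolysis genes had a higher median than nearly all random lists. Of 16 measured, 7 were higher and 0 lower (median 0.70, percentile 99.94), with 8 higher after median centring. Pfkfb3, which makes the activator of phosphofructokinase, was 42.2-fold higher, the glucose transporter gene Slc2a1 6.87-fold, the hexokinase gene Hk2 4.44-fold and Pfkp 3.32-fold, while Pdk1 was at -0.45. The other Pfkfb3 probe set was at 2.70 on the log2 scale. As deposited, 9 members lay within 2-fold, so the list did not rise as a whole. Among these 9 were the enzyme genes Aldoa (-0.17), Pgk1 (0.07), Pgam1 (0.01), Pkm (-0.05) and Ldha (0.42). All of these but Ldha change sign under at least 1 scaling. Gapdh, Eno1 and Gpi1 had no single-gene probe set. Of 19 measured genes of the TCA cycle and oxidative phosphorylation, 1 was higher, 2 were lower (1 after median centring) and 16 lay within 2-fold. Their median of -0.11 (percentile 56.2) turns positive after median centring, loess and scaling to the poly-A controls. The isocitrate dehydrogenase genes Idh1 and Idh2 were 3.48-fold and 1.70-fold lower. Idh3a, also an isocitrate dehydrogenase gene, was at 0.40, with its 4 probe sets from -0.14 to 0.76 on the log2 scale. The fumarase gene Fh1 was 2.43-fold lower and the cytochrome c gene Cycs 4.21-fold higher.

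Sterol genes did not move as a block. Of 16 measured cholesterol synthesis genes, 1 was higher and 3 lower (median 0.06, percentile 93.5, and -0.19 with the median of each gene's probe sets), and after median centring 4 were higher and 2 lower. Dhcr7, Stard4 and Mvk were 3.53-fold, 3.38-fold and 2.53-fold lower by their brightest probe sets, and Idi1 was 2.16-fold higher. The 3 probe sets of Stard4 ranged from -1.76 to -0.30 and the 2 of Mvk from -1.34 to -0.29, so that Mvk rests on 1 of its 2 probe sets. Of 11 measured LXR targets and cholesterol efflux genes, 1 was higher and 2 lower (median -0.76, percentile 3.67), and 3 of the 11 alternatives put the list below the 2.5th percentile, at 1.33 in the lowest. Scd2, Npc1 and Apoc2 were 7.13-fold, 4.86-fold and 1.99-fold lower. The 1 higher member was Ch25h, which encodes cholesterol 25-hydroxylase, at 30.5-fold. As deposited, the quartiles of this list were -0.94 and -0.48, so most of its members were below 0.

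Stress and degradation lists lay inside the range of random lists. Of 13 measured NRF2 and oxidative stress genes, 3 were higher and 5 lower (median -0.62, percentile 8.63), but 5 were higher and 4 lower after median centring. The metallothionein gene Mt2 was 4.89-fold higher and the cystine transporter gene Slc7a11 at least 3.82-fold higher, while Gclc, of glutathione synthesis, was 6.75-fold lower. Of 15 measured genes of the unfolded protein and amino acid response, 0 were higher and 2 lower (median -0.37, percentile 30.3). After median centring the median turns positive, with 2 higher and 1 lower. Ern1, the gene of the endoplasmic reticulum stress sensor IRE1, was 4.28-fold lower (3 probe sets, from -2.10 to -0.56) and Dnajb9 2.12-fold lower, with Trib3 at -0.99 and Chac1 at 0.77. Of 17 measured lysosome and autophagy genes, 0 were higher and 3 lower (median -0.34, percentile 7.21, positive after median centring). Tfeb, a regulator of lysosomal genes, was at least 10.5-fold lower, the autophagy kinase gene Ulk1 5.57-fold and the acid lipase gene Lipa 3.12-fold, while Atg7 was at -0.96. Sqstm1 was at 0.23, with its other probe set at -1.19. With plain probe sets alone the lysosome list had a median of -0.96 at percentile 0.39.

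**Figure D3:**
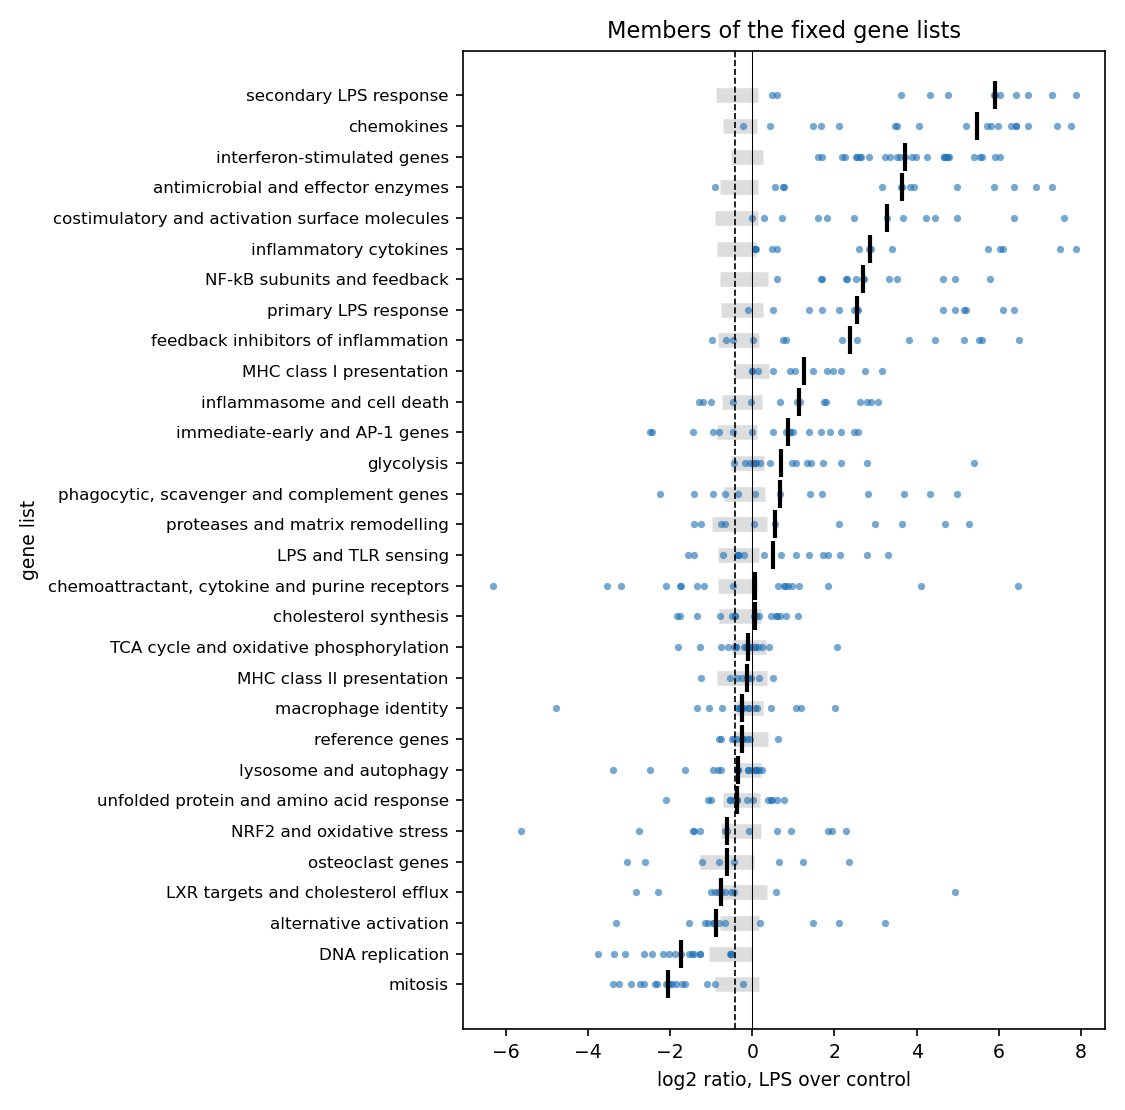
Log2 ratio of the LPS over the control array (x axis) for the measured members of the 30 fixed pathway lists (y axis), with blue points for genes, black bars for list medians and grey bands for the 2.5th to 97.5th percentile of the medians of 10000 random lists matched on signal. Members under the control floor whose floored ratio was 0 or less have no point but count in the medians. The dashed line marks the median of measured genes, -0.42, and the lists run from secondary LPS response genes, at 5.90, to mitosis genes, at -2.06, while medians close to 0 change sign with the scaling.

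Reference genes, often used to normalize expression, differed little. Of 11 measured, 0 were past 2-fold in either direction (1 higher after median centring), and the median of -0.26 (percentile 21.0) turns positive after median centring and after scaling to the poly-A controls. Tfrc, Gusb and Hprt were at -0.80, -0.76 and -0.48, and Ywhaz was at 0.64, although its 7 probe sets ranged from -0.20 to 0.94.

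Markers of other cell types that a bone marrow culture could hold were mostly under the floor. Of the 9 neutrophil markers with a single-gene probe set, 5 were measured, with 1 higher and 0 lower (median 0.67, percentile 99.10) and 3 higher after median centring, beside the higher inflammatory lists. Csf3r was 2.18-fold higher, S100a8 and S100a9 were at 0.71 and 0.67 from control signals of 270 and 96.0, and Ngp was at -0.31, positive under 3 of the 5 scalings. This list lay inside the range of the random lists in 3 of the 11 alternatives, at percentile 94.7 in the lowest. T cell markers had 2 measured members: Cd8a, with signals of 70.3 and 44.3, and Cd28, the costimulatory receptor of T cells, with signals of 2197 and 72.0, 30.5-fold lower. The NK cell list had 1 measured member, Prf1, with signals of 34.5, under the floor, and 29.0. Of the B cell list 3 were measured (median -1.19, percentile 12.3), with Cd79b 3.11-fold lower, Cd22 2.29-fold lower and Vpreb1 at 40.8 on the control array and under the floor on the LPS array, and 1 was lower after median centring. All were under 110 signal units on the control array.

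The other marker lists were as sparse. Of the dendritic cell list 3 were measured (median -0.04, percentile 83.8, positive under all 5 scalings). Itgax was at -0.04, positive under all 5, Batf3 at -0.42, positive under quantile normalization and loess, and Zbtb46 had signals of 18.5, under the floor, and 50.2. Of the mast cell or basophil list 3 were measured (median 0.28, percentile 96.1). Hdc, which encodes the histamine-forming enzyme, was at least 24.5-fold higher from a control signal of 3.21 to 861 on the LPS array, while Gata2 was at 0.28 and Kit had signals of 39.5 and 10.7, the latter under the floor. Of the erythroid list 2 were measured, Epor at -0.31, positive under 3 of the 5 scalings, and Klf1 with signals of 32.1, under the floor, and 40.0. Of the megakaryocyte list 3 were measured (median -0.26, percentile 54.9, positive after median centring and after scaling to the poly-A controls). Pf4 had signals of 6623 and 5537. Of the stromal list 3 were measured (median 0.19, percentile 94.1, and -0.26 with the floor at the 35th percentile), with Pdgfrb at least 4.85-fold higher from a control signal of 3.97. Of the endothelial list 4 were measured (median -0.13, percentile 85.7, positive under 4 of the 5 scalings), with Vwf 8.38-fold lower and Kdr 3.53-fold higher. The sign of this median comes from Cdh5 and Pecam1, whose control signals of 15.7 and 4.10 were under the floor and whose LPS signals of 29.8 and 34.5 lay between the 2 arrays' floors. This list lay above the random lists with the floor at the 35th percentile and with the pseudocount, with medians of 0.83 and 0.93 and percentiles of up to 99.8.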

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

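The tests on the hybridization controls, the poly-A controls, the progenitor markers and both Cd28 tests were chosen only after the result was seen. The criteria of the progenitor and T cell tests were also revised with the values known, and their verdict changed with the criterion. A criterion that asks for a 2-fold fall leaves both explanations open, since 0 of 6 progenitor markers and 1 of 8 T cell genes were bright enough on the control array to show one. The number of markers at the floor, given below, was made the criterion when that number was known, so it decides neither explanation.

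Probe sets listed with no gene or with several genes stood outside the comparisons by gene, and 253 of the 3774 measured were at least 2-fold higher on the LPS array than on the control array. That is 6.7%, beside 8.2% of the named genes, and 211 of them were listed with no gene and 42 with several. A further 662 (17.5%) were at least 2-fold lower, beside 26.2% of named genes, and after median centring the numbers were 410 higher and 338 lower. The sources used here name no single gene for them, and no explanation was tested.

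The median gene was lower on the LPS array by a log2 ratio of -0.42. Weaker hybridization or scanning of that array would lower the hybridization controls as much as probe sets of equal brightness, but their median was -0.048 (SD 0.12) against -0.23. That argues against it as the whole cause only if equal amounts of these controls were added to both arrays. Less efficient labelling of the LPS sample cannot be told apart from the LPS condition here, since the poly-A controls had a median of -0.29 (SD 0.23), more than 1 SD from both 0 and the -0.59 of probe sets of equal brightness. Both SDs are over probe sets that read a few added transcripts, dap, lys, phe and thr or bioB, bioC, bioD and cre. They do not measure the error of the amounts added to each array. A larger share of signal taken by higher genes also stays open as a part of the cause: the 2022 probe sets at least 2-fold higher held 4.8% of the total signal on the control array and 22.9% on the LPS array, which at equal totals would lower all others by a log2 ratio of -0.30. These probe sets were picked by the same ratio, so their share had to be larger. Such a share would by itself lower dim and bright genes alike, whereas the medians were -0.61 at a mean log2 signal of 7 to 9 and -0.08 at 11 to 14. An effect of LPS on many transcripts stays open as well and is untested.

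DNA replication and mitosis genes were lower together, with a median of -1.97 over their 34 measured members. If the array-wide shift and its dependence on brightness were the cause, loess would bring this median near 0, but it was -1.61 after loess, with 25 members still at least 2-fold lower. Myeloid progenitors would bring their abundant transcripts, but only 1 of 6 early progenitor markers, Kit at 39.5, reached the floor on the control array, while Mpo, Elane, Prtn3, Ctsg and Cd34 were under it. Most of these markers were thus not seen above the floor, but a criterion set with these values known does not decide whether progenitors were a source. A lower share of dividing macrophages with LPS may account for the pattern, as a hypothesis that 1 array per condition cannot separate from a difference between the cultures.

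Cd28 had signals of 2197 on the control array and 72.0 on the LPS array. T cells would bring their other abundant transcripts, but only 1 of 8 T cell receptor complex and surface genes, Cd8a at 70.3, reached the floor on the control array, while Cd3e, Cd3d, Cd3g, Cd4, Cd5, Cd2 and Thy1 were under it. The criterion was set with these values known, so it does not decide whether T cells were the source. A faulty probe set would show a difference that the other one lacks, but the other Cd28 probe set had 2001 and 72.4, a log2 ratio of -4.79. Expression of Cd28 by untreated macrophages is a candidate explanation that was not tested on independent data.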

How the results depend on the processing

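The alternatives that scale to the spiked controls or keep only genes measured on both arrays were added after the data were seen. The count of lower genes depended on the scaling: from 3076 as deposited it went to 1828 with quantile normalization, 1818 with median centring and 1717 with loess, while the count of higher genes went from 964 to 1513 with median centring. These scalings remove the array-wide shift by construction. At 3-fold the counts were 612 higher and 1428 lower, and at 1.5-fold 1524 and 4926, by construction of the threshold. The other alternatives gave counts within 1.5 times the deposited ones. Of the 37 fixed lists with a percentile, 17 lay above and 3 below the random lists, and 14 of the 17 and 2 of the 3 kept that side in every alternative. The exceptions were the phagocytic, protease, neutrophil and alternative activation lists, and the cause was not tested. No paired analysis was possible because each condition has 1 array, and no array could be left out. Signals near the floor limit the ratios of dim genes: 1055 genes were measured only on the LPS array and 845 only on the control array, and their folds are bounds.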

Other observations

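The grouping of genes by symbol stem, its bounds and the FoxO-induced and clock lists were chosen after the ratios were seen, so neither list is independent evidence for its hypothesis, although the outcomes that would count for and against it were written down before the percentiles were computed.

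Grouping measured genes by the stem of their symbol gave 195 stems with at least 8 members. At or below percentile 0.1 of matched random lists lay 3 stems and at or above 99.9 lay 7, where 0.39 would lie outside by chance. A stem is a shared name and not always a family. The Slfn genes, which encode Schlafen proteins of immune cells, were higher in 7 of 8 measured members with a median log2 ratio of 2.28. The Parp stem, of ADP-ribosyltransferases, had 5 of 11 higher and 3 lower (median 0.89). Chosen after their values were seen, Parp9 and Parp14, often induced by interferon, were at 1.99 and 2.60, while Parp1 and Parp2, of DNA repair, were at -1.22 and -1.29. The Ifi stem had 7 of 11 higher (median 1.09, and 3.23 with plain probe sets alone), the Il stem 14 of 43 higher and 6 lower (median 0.30, and 1.05 with the floor at the 65th percentile), and the Col stem a median of 0.13 with 2 of 19 higher and 1 lower. The Ccl and Cxcl stems, at 3.53 and 5.46, overlap the chemokine list, and the Cxcl median was 2.11 with only genes at or above the floor on both arrays. Other stems share members with the fixed lists too, such as Il6 and Il1b of the Il stem, Ifi204 of the Ifi stem and Kif11 of the Kif stem.

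On the lower side, the Kif stem, of motor proteins of which many act in mitosis, had 16 of 27 lower and 0 higher, with a median of -1.47 that was -0.92 after loess. The Cep stem, of centrosomal proteins, had 20 of 36 lower and 0 higher (median -1.18, and -0.69 after loess). The Zfp stem, of zinc finger proteins, had 111 of 265 lower and 8 higher. As deposited, its median was -0.93, against a median of -0.57 for random lists of equal brightness. The Zfp median was -0.52 after median centring and -0.39 after loess. The medians of all 10 stems kept their sign in each of the 11 alternatives.

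Sesn1, among the lowest genes, and Klf2 are known targets of FoxO transcription factors, which led to the hypothesis that FoxO-driven transcription may be lower with LPS. A list of other FoxO-induced genes was then drawn up. Of 19 measured members of such a list, 11 were at least 2-fold lower and 1 higher, with a median of -1.41 at percentile 0.00, below all 10000 random lists, and 2 were higher and 10 lower after median centring. The percentile stayed at or under 1.86 in all 11 alternatives, and the median was -0.82 with quantile normalization and -0.81 with loess. Foxo3 itself was 10.9-fold lower, the interleukin-7 receptor gene Il7r 11.4-fold, and S1pr1 10.7-fold, and Klf9 was at -3.81 with its LPS signal under the floor and its 5 probe sets reaching up to -0.82, while Bcl6 was 2.24-fold higher with its other probe set at 0.49. Transcript levels do not measure FoxO activity, and many of these genes have other regulators.

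Dbp was among the lowest, which led to the hypothesis that the circadian clock may stand at another phase or level with LPS. Of 11 other measured clock genes, 6 were at least 2-fold lower and 0 higher, with a median of -1.40 at percentile 0.80, but after median centring 2 were higher and 5 lower. Clock genes peak at different times of the cycle, so this median cannot test a change of phase and describes only the level of the list. Arntl was at -0.99 (its other probe set at 0.29), Clock at -0.51 and Cry1 at 0.79. The list lost its place below the random lists in 3 of the 11 alternatives, with percentiles up to 17.9, namely with floors at the 35th and 65th percentile and with genes measured on both arrays alone. Bhlhe40 was at least 7.77-fold lower, Tef 6.44-fold, Nr1d2 6.18-fold and Per3 at least 4.33-fold (5 probe sets, up to -0.48), while Ciart had signals of 33.6, under the floor, and 68.2, so that its log2 ratio is at least 0.96. A difference in the time of day at harvest between the cultures, which the labels do not give, stays open.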
